A study of Gallus gallus with 10 samples.

How the data were processed

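RNA from whole brains of chicken embryos was measured on Affymetrix chicken arrays, 1 array per sample, with 5 male and 5 female samples per the labels. The labels give sex as the group and describe the material as total RNA from dissected whole brain. Embryonic age, breed, the number of animals behind each sample and the hybridisation dates are not given in the sources used here. Because nothing says whether each sample came from a separate embryo, p-values measure the spread between these samples, which may be partly technical. The letters in the sample titles do not say that male and female samples form pairs, and sexes were compared without pairing. The title of male replicate 1, unlike the others, gives neither a letter nor the sex, which was taken from its description.

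The deposited values are intensity values on a linear scale, 1 per probe set, for 38535 probe sets on each of the 10 arrays. The summary method and software behind them are not given in the sources used here. On every array the mean after removing the highest and lowest 2% of the deposited intensity values was 2500, so the values had been scaled per array before deposit. Median intensity per array ran from 592 to 720. The number of arrays limits the precision, and no detection calls were used here.

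Values were taken as log2(intensity + 16), without further normalization and without a filter on dim probe sets. A pseudocount lowers the fold change of dim genes, so fold changes are on the log2(intensity + 16) scale. The 96 control probe sets of the manufacturer were left out, which left 38439. Of these, 27168 had 1 gene symbol in the platform annotation, 177 had several and 11094 had none, and no gene was named from a probe set with several. Platform gene identifiers were updated through a reference gene table of the assembly bGalGal1.mat.broiler.GRCg7b, which was used for symbols, chromosome names and gene order. No coordinates are given, since the build behind the array design is not given in the sources used here. Of 13051 genes, 12872 were matched by gene identifier, 1 by accession and 178 were not matched. They comprised 12229 autosomal, 606 Z, 17 W and 199 unplaced genes. Each gene was represented by its probe set with the highest mean over the 10 arrays. Some listed symbols were matched through synonyms to related genes, such as ALAS1 for ALAS2 and PKLR for PKM. Among the 38439 were 689 probe sets with identifiers of viral sequences, 687 of them without a single gene name, and they served as a reference for background.

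The sexes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, male minus female), with Benjamini-Hochberg adjustment over all probe sets or over all genes and a threshold of 0.05. Errors of a difference are limma's moderated standard errors, and errors of a group mean are SDs over 5 arrays. A gene was called expressed if its mean log2 value over the 10 arrays was at least 9.33, the median of the tested probe sets, which is an intensity of 626. Differences between gene groups used an index per array, the median over a gene group of each value minus the gene's mean over all arrays, minus the same median over the other group. The sex labels of this index were permuted exactly over the 252 arrangements of the 10 arrays, two-sided, and the smallest p this allows is 0.00794. This p covers the spread between arrays for a fixed group of genes, and does not say whether other Z genes would differ as much. For that, 2000 random groups of expressed Z genes of the same size were drawn, a test chosen after the results were seen. The Z share among genes higher in males was tested with Fisher's exact test, and genes are not independent replicates. Chromosomes with at least 20 genes and gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry.

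The choices of test, gene lists and alternatives were made before the data were examined, except where stated. The named genes followed a fixed rule at gene level: among genes past the threshold, the 10 Z genes most above in males, up to 5 Z genes above in females, the 6 autosomal genes most above in each sex, up to 6 W or unplaced genes above in females and up to 3 members of each list. DMRT1, HINTW, CHD1, NTRK2, GHR, PRLR, HSD17B4, CYP19A1 and ESR1 were named whatever their values. Another item of this rule is not reported here. The 31 lists covered Z genes with a known W copy, sex determination, steroid synthesis, hormone receptors, hypothalamic peptides, neurotrophins, Z immune genes, neuronal and glial cell types, blood, vessel, meninges and choroid plexus, tissues beside the brain (eye, pituitary, muscle) and cell processes.

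Alternatives were quantile normalization, centring on autosomal genes, other pseudocounts, other filters on dim genes, removal of probe sets prone to cross-hybridisation, the mean over probe sets of a gene, other variance models, array weights, other window sizes, leaving out each array in turn and a block on the title letters. On simulated data with 200 of 38439 probe sets changed between 5 and 5 arrays, the limma comparison recovered 4% of 50 probe sets changed 1.3-fold, 32% at 1.5-fold, 78% at 2-fold and 98% at 4-fold, and 6 of 112 calls were false. The changed probe sets were drawn from those at or above the expressed level, with independent normal noise. Recovery of dimmer probe sets was not simulated. In the same kind of test a Z shift of 0.4 was returned as 0.41 by the index, and 2 of 40 comparisons without a shift gave a permutation p under 0.05. That check covers the index of Z against autosomal genes only. In contrasts between groups of Z genes, 35.75% to 38.55% of the random draws gave a permutation p under 0.05.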

Results

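The series compared gene expression between whole brains of male and female chicken embryos, with 5 arrays per sex. In birds the male carries ZZ and the female ZW sex chromosomes, so the comparison addresses how a difference in Z copy number appears in brain RNA, and which genes off the sex chromosomes differ between the sexes. The arrays were alike in scale. Pairwise correlations of log2 intensity across all tested probe sets ran from 0.918 to 0.946, a description across genes that are not independent replicates, and no pair of arrays was identical. The ratio of 3' to 5' signal of actin ran from 1.08 to 1.33. Virus probe sets, the background reference, had a median log2 level of 5.41 on male replicate 1 and 6.32 on female replicate 3, the lowest and highest of the arrays. Their median male minus female difference was -0.18, against -0.02 for expressed autosomal genes. The other males had virus medians of 5.93 to 6.18 and the females of 5.71 to 6.32, so male replicate 1 weighs on the virus difference. In limma, 247 probe sets were higher in males and 60 higher in females after Benjamini-Hochberg adjustment, and 2633 had an unadjusted p under 0.05. Of the 689 virus probe sets, 2 passed the same threshold, both higher in males, at 2.03 and 2.08.

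Among named genes, W-linked genes showed the largest measured differences. HINTW, a W-linked member of the HINT family, had a mean log2 level of 16.72 ± 0.15 in females and 7.12 ± 1.52 in males (SD, n = 5 each), a difference of -9.59 (SE 0.63, limma adjusted p = 0.000107). LOC107049459 differed by -6.27 (SE 0.27), the spindlin gene SPIN1L by -5.42 (SE 0.41), LOC374195 by -5.24 (SE 0.31), LOC430910 by -5.18 (SE 0.17) and UBE2R2L, a ubiquitin-conjugating enzyme gene, by -4.62 (SE 0.33). Male levels of these genes lay between 5.48 for SPIN1L and 8.16 for LOC430910, below the expressed level of 9.33, so the sizes of these differences depend on background. Of 17 genes placed on W, 10 were higher in females by limma, and in 10 every female array exceeded every male array, an order that 0.397% of arrangements give by chance. The other W-placed genes did not pass. MBD2 differed by -0.07 (SE 0.08, adjusted p = 0.918). NEDD4L differed in the male direction by 0.59 (SE 0.13, adjusted p = 0.0729), with 5 of 5 males above all females. W and Z copies can share probe sequence, so levels of W-placed genes with a Z copy are uncertain.

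**Figure D1:**
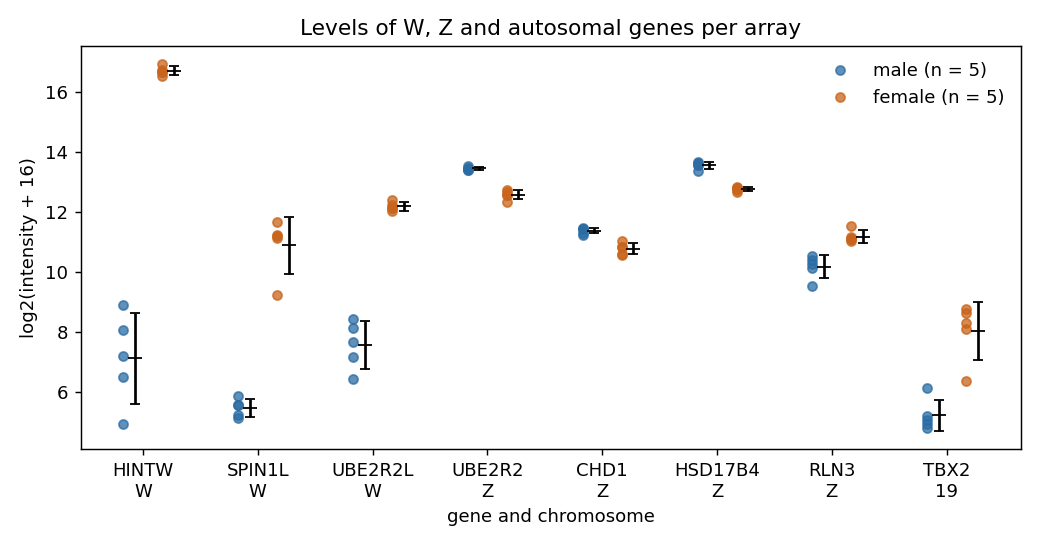
Log2(intensity + 16) of 8 genes on each array, males in blue and females in orange, with black bars for the mean and SD over 5 arrays. HINTW averaged 16.72 in females and 7.12 in males, whereas UBE2R2 on Z averaged 13.47 in males and 12.59 in females.

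Z-linked genes made up nearly all genes higher in males. MAT2L was higher in males by 2.53 (SE 0.25, limma adjusted p = 0.000446), although its female level of 6.01 was under the virus median of 6.16, so the size is not measured. The 2 virus probe sets past the threshold had levels of 8.05 and 7.20 in males and 5.97 and 5.18 in females. MAT2L, at 8.54 in males, had a somewhat larger difference, but background probe sets can give this direction too. YTHDC2, an RNA helicase gene, was higher by 1.44 (SE 0.27), the protease-activated receptor gene F2RL2 by 1.27 (SE 0.19), NUDT2, a dinucleotide hydrolase gene, by 1.22 (SE 0.13) and the intraflagellar transport gene IFT74 by 1.16 (SE 0.08). NDUFAF2, a complex I assembly factor gene, was higher by 1.15 (SE 0.22), HAUS6 of the augmin complex by 1.14 (SE 0.19) and the sulfatase gene ARSK by 1.09 (SE 0.16). The mitochondrial ribosome gene MRPS30 (log2 SE 0.13) and SPTLC1, a subunit of serine palmitoyltransferase (log2 SE 0.07), each had a male to female ratio of 2.14. In each of these 10 genes all 5 males exceeded all 5 females. The 6 probe sets of YTHDC2 ran from -0.06 to 1.44, and 1 passed the threshold over all probe sets. Of the 2 probe sets of NDUFAF2, 0 passed it, and each of the other genes had at least 1 that did. Limma adjusted p of the 10 genes ran from 0.000107 for SPTLC1 to 0.0286 for YTHDC2 and NDUFAF2.

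In all, 201 of 606 Z genes (33.2%) were higher in males and 2 were higher in females, adjusted over all genes. Adjusted over Z genes alone, 306 were higher in males and 5 in females. A positive difference was seen in 499 of 606 (82.3%). Every male array exceeded every female array in 255 Z genes (42.1%) and in 23 autosomal genes (0.188%), and every female array exceeded every male array in 81 autosomal genes (0.662%), where chance gives 0.397% in each direction. Z genes were 97.6% of the Z and autosomal genes higher in males and 4.72% of those tested (odds ratio 1172, 95% interval 494 to 3874, Fisher's exact p = 1.77e-273 over genes). The 2 Z genes higher in females with the adjustment over all genes were RLN3 and ZSWIM6. RLN3, which encodes the neuropeptide relaxin 3, differed by -1.01 (SE 0.19, limma adjusted p = 0.0259) and ZSWIM6 by -0.71 (SE 0.14, adjusted p = 0.0372). ZSWIM6 had 3 probe sets, of which 1 carried this sign, and RLN3 had 1. With the adjustment over all probe sets, 0 of these passed. ZSWIM6 is on the list of Z genes with a known W copy, and without probe sets prone to cross-hybridisation it differed by 0.10. Whether its chosen probe set also reads the W copy was not tested. A further gene identifier under the name ZSWIM6, unplaced in the assembly, differed by -0.87 (SE 0.17, adjusted p = 0.0328).

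The Z chromosome as a whole was shifted toward males. Expressed Z genes (445) had a median difference of 0.47, a male to female ratio of 1.39, and expressed autosomal genes (8728) had a median of -0.02, a ratio of 0.989. The Z minus autosome index was 0.26 ± 0.02 in males and -0.26 ± 0.02 in females (SD, n = 5 each), a difference of 0.52 or a ratio of 1.43 (exact permutation p = 0.00794, the smallest possible). All 5 males lay above 0 and all 5 females below. Camera called Z as the only chromosome of the 32 tested (adjusted p = 3.59e-86, and adjusted p = 6.6e-10 with an estimated correlation). Chromosome 25 had the next lowest adjusted p, 0.123.

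**Figure D2:**
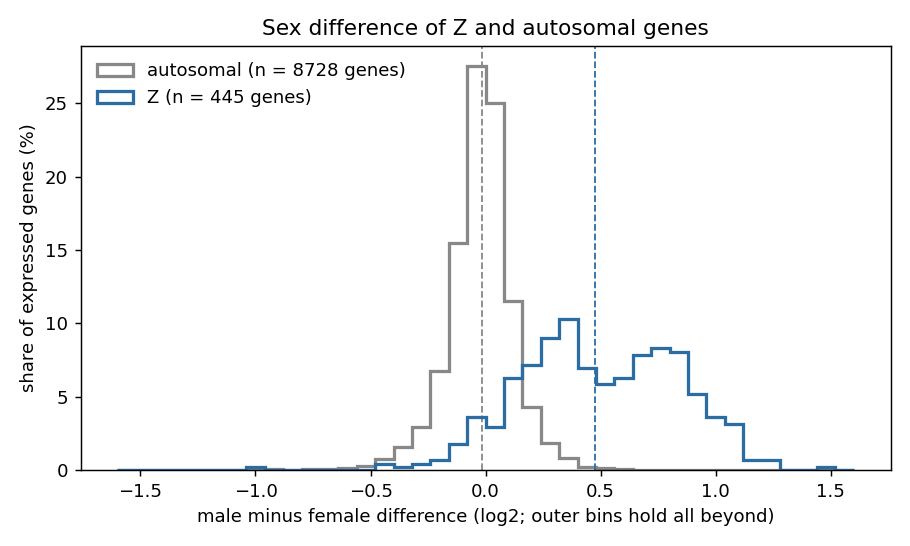
Distribution of male minus female log2 differences over 445 expressed Z genes (blue) and 8728 expressed autosomal genes (grey), each as a share of its class, with dashed lines at the medians of 0.47 and -0.02. The Z distribution is shifted to positive values and is wider.

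**Figure D3:**
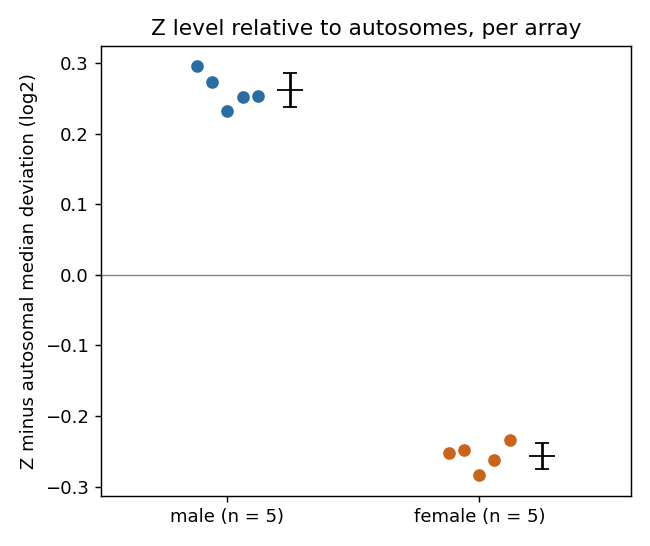
Z minus autosome index of each array (points) with the mean and SD of 5 arrays per sex (black). Males averaged 0.26 and females -0.26 on the log2 scale.

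Z genes differed from each other in the size of the male excess. Among expressed Z genes, 14.4% (64) had a male to female ratio under 1.1, 25.4% (113) from 1.1 to 1.3, 17.1% (76) from 1.3 to 1.5 and 43.1% (192) at 1.5 or more, and 11.2% (50) reached 1.9. A ratio under 1 was measured for 7.42% (33). Of expressed autosomal genes, 90.2% had a ratio under 1.1 and 0.115% (10) reached 1.5. The interquartile range of the differences was 0.52 over Z genes and 0.15 over autosomal genes, 3.45 times as wide. The SD was 0.34 and 0.15, and after subtracting the mean squared standard error it was 0.31 and 0.05.

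Z genes whose W copy is known had a higher median male excess than other Z genes, by an amount that random groups of Z genes also reached. UBE2R2 was higher in males by 0.88 (SE 0.08, limma adjusted p = 0.000259), RASA1, a regulator of Ras signalling, by 0.88 (SE 0.09, adjusted p = 0.000478) and the chromatin remodeller CHD1 by 0.61 (SE 0.10, adjusted p = 0.0106). The median over 16 expressed genes of this kind was 0.62 (ratio 1.54), against 0.46 (ratio 1.38) over the other 429, and 13 of the 16 were higher in males. The index differed by 0.15 between the sexes (exact permutation p = 0.00794), which holds for these 16 genes across arrays. Among 2000 random draws of 16 expressed Z genes, 275 gave a difference as large in either direction. As a list, the 21 measured members included W-placed NEDD4L and LOC427025 and the unplaced ZSWIM6. Of these, 13 were higher in males, 2 (both ZSWIM6 identifiers) were higher in females and 6 did not pass, and adjusted over the list alone 17 and 2 passed. Camera, which sets a list against all other genes, called it with adjusted p = 1.83e-25 and adjusted p = 7.55e-05 with an estimated correlation. Since 18 of the 21 members lie on Z, that call does not bear on a difference from other Z genes.

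The 40 Z genes around DMRT1, the gene for a male-determining transcription factor, had a smaller male excess than the other Z genes, though other stretches of Z were as low. The 40 expressed genes nearest to it in gene order had a median difference of 0.34 (ratio 1.27), against 0.50 (ratio 1.41) over the other 405, and 10 of the 40 were higher in males. The index was -0.08 ± 0.05 in males and 0.07 ± 0.05 in females (SD, n = 5 each), a difference of -0.15 (exact permutation p = 0.00794). Its size depended on the choices: -0.24 with a window of 20 genes, -0.094 with a window of 80 (exact permutation p = 0.00794 for both) and -0.080 with the filter that kept the brightest genes (exact permutation p = 0.0159). DMRT1 itself was below the expressed level and differed by 0.07 (SE 0.29, limma adjusted p = 0.979), with 4 of its 7 probe sets above 0. Medians of the 406 windows of 40 consecutive expressed Z genes ran from 0.27 between APH1AL and HMGCS1 to 0.74 between PELO and CDK7, and 8.87% of the windows were as low as the one at DMRT1. The windows overlap, some of them with the one at DMRT1, so this share is a description. Of 2000 draws of 40 Z genes without regard to position, 48 differed as much in either direction.

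**Figure D4:**
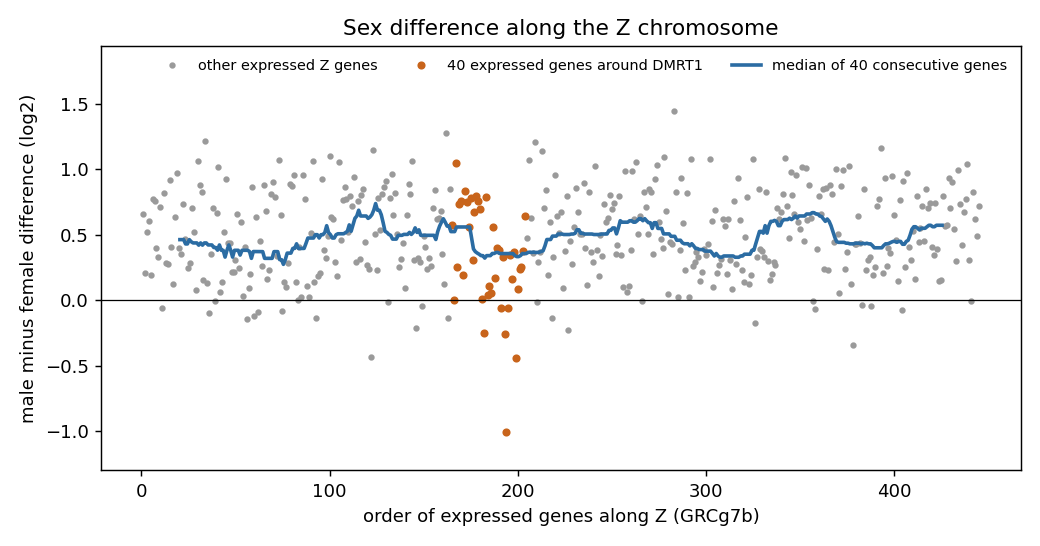
Male minus female log2 difference of each expressed Z gene in its order along the chromosome, with the 40 genes around DMRT1 in orange and the median of 40 consecutive genes as a blue line. The line runs from 0.27 to 0.74, and the window at DMRT1 lies at 0.34.

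Whether the male excess of Z differed by expression level depended on the filter, which sets the Z genes compared, and on the processing. With expressed Z genes split into 3 groups by level, the brightest group (149) had a median difference of 0.43 and the dimmest (148) of 0.46, and the index differed by 0.01 (exact permutation p = 0.754). With no filter on dim genes the difference was 0.28 (exact permutation p = 0.0159), and with a stricter filter that kept the brightest genes it was -0.20 (exact permutation p = 0.00794). With the same filter as first used, it was -0.030 after quantile normalization (exact permutation p = 0.00794) and 0.079 at the highest pseudocount (exact permutation p = 0.0238). Random groups of expressed Z genes of the same size differed by -0.091 to 0.091 in the central 95% of draws. These were drawn with the filter and processing first used, so the range does not cover the other filters.

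Few autosomal genes passed the threshold, and none did when autosomal genes were adjusted alone. Adjusted over all genes, 5 of 12229 were higher in males: PIK3R6, a regulatory subunit of a phosphoinositide kinase, by 1.45 (SE 0.24), the sphingomyelinase gene SMPD2 by 1.37 (SE 0.24), the lactase gene LCT by 0.92 (SE 0.18), the muscle ubiquitin ligase gene TRIM63 by 0.66 (SE 0.14) and FLT1, a receptor for vascular endothelial growth factor, by 0.32 (SE 0.06). Their limma adjusted p ran from 0.0121 for PIK3R6 to 0.049 for TRIM63. Higher in females were 13, among them the T-box gene TBX2 at -2.81 (SE 0.46, adjusted p = 0.0121), MYO15L at -2.34 (SE 0.44), C17orf78 at -2.10 (SE 0.39), TSNAXIP1 at -1.85 (SE 0.37), LOC429032 at -1.28 (SE 0.23) and the immunoglobulin-like receptor gene CHIR-A2 at -0.87 (SE 0.10, adjusted p = 0.00122). All 5 arrays of the higher sex lay above the other sex in these genes except TSNAXIP1, with 4 of 5. Adjusted over autosomal genes alone, limma called 0 in either direction, with 621 at an unadjusted p under 0.05 and the lowest adjusted p, 0.0928, for CHIR-A2. At the unadjusted p of 0.000878 that the calls reach, chance gives about 10.7 autosomal genes. Most were dim: 5 of the 18 met the expressed level, and TBX2 averaged 8.04 in females and 5.23 in males. Male means of TBX2, MYO15L (5.96), C17orf78 (6.13) and TSNAXIP1 (5.63) lay under the virus median of 6.16, so the sizes of these differences depend on background and give no order. Virus probe sets, which are dim, had a median difference of -0.18, on which male replicate 1, their lowest array, weighs. The probe sets of LCT, TRIM63, FLT1, MYO15L, C17orf78 and TSNAXIP1 did not pass the threshold over all probe sets. Other probe sets of LCT, FLT1, MYO15L and CHIR-A2 had the opposite sign, and leaving out male replicate 3 left 1 autosomal gene higher in males. The 13 higher in females became 6 without male replicate 1 or 5 or female replicate 3 or 4, and 8 without male replicate 2 or 4.

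Among the genes of steroid and hormone signalling, HSD17B4 on Z passed the threshold. The gene, which encodes a peroxisomal enzyme of steroid and fatty acid metabolism, was higher in males by 0.79 (SE 0.07, ratio 1.73, limma adjusted p = 0.00028), with 5 of 5 males above all females. CYP19A1, which encodes aromatase, differed by 0.62 (SE 0.45, adjusted p = 0.859) and the estrogen receptor gene ESR1 by 0.02 (SE 0.40, adjusted p = 0.993). On Z, the neurotrophin receptor gene NTRK2 differed by 0.35 (SE 0.09, adjusted p = 0.106), the prolactin receptor gene PRLR by 0.33 (SE 0.26, adjusted p = 0.871) and the growth hormone receptor gene GHR by 0.14 (SE 0.13, adjusted p = 0.899), and none of these passed. All 5 males exceeded all females for NTRK2, and the 2 probe sets of GHR differed in sign. Of the 16 measured genes of steroid synthesis, HSD17B4 alone passed, also when adjusted over the list alone (camera adjusted p = 0.326). Estimates of others were imprecise, such as 0.78 (SE 0.41) for HSD17B1 and -0.99 (SE 0.55) for HSD3B1, so differences of this size were not excluded. Of 14 sex determination genes, 16 genes of nuclear hormone receptors and cofactors and 15 genes of hypothalamic peptides and receptors, 0 passed by limma, where 234 of all 13051 genes passed and 995 had an unadjusted p under 0.05 (camera adjusted p = 0.829, 0.679 and 0.996). Of 9 neurotrophin genes, 0 passed over all genes, and 1, NTRK2, passed adjusted over the list alone (adjusted p = 0.0209, camera adjusted p = 0.996). Of 8 Z genes of immune, cytokine and related signalling, among them the kinase gene JAK2 and the interferon gene IFNW1, 4 had a positive difference and 0 passed (camera adjusted p = 0.984). Over all 606 Z genes, 82.3% had a positive difference and 33.2% were higher in males past the threshold over all genes. Camera sets the list against all other genes, so its p does not compare these 8 with other Z genes.

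Cell type and process lists showed no sex difference past the threshold. In the list of oxidative phosphorylation genes, the Z genes NDUFS4 at 0.86 (SE 0.07), COX7C at 0.63 (SE 0.06) and ATP5F1AZ at 0.47 (SE 0.08) were higher in males and 31 of 34 did not pass (median -0.01, camera adjusted p = 0.679). The other probe set of NDUFS4 differed by 0.11, and 1 of its 2 probe sets passed the threshold over all probe sets. The probe set of ATP5F1AZ did not pass it. DNAJA1 on Z, a co-chaperone gene, was higher by 0.46 (SE 0.06) among 15 heat shock genes (median -0.02, adjusted p = 0.984), and FLT1 was the member that passed among 15 vessel genes (median -0.03, adjusted p = 0.829). Adjusted over the list alone, these 3 lists gave 3, 1 and 1 genes. The 11 choroid plexus genes had a median of -0.15, with 2 of 11 positive and 0 past the threshold (camera adjusted p = 0.058, and adjusted p = 0.955 with an estimated correlation). Among them CLIC6 differed by -0.78 (SE 0.24, limma adjusted p = 0.294) and transthyretin, TTR, by -0.12 (SE 0.10, adjusted p = 0.885). Choroid plexus passed in some alternative settings, for instance at adjusted p = 0.0123 without male replicate 2.

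The remaining lists had no member past the threshold, also adjusted over the list alone. Median differences of neuronal lists were -0.03 for 13 glutamatergic genes, -0.02 for 13 GABAergic genes, 0.01 for 16 synapse genes and -0.14 for 13 monoaminergic and cholinergic genes. For other cells of the brain they were -0.04 for 13 progenitor genes, -0.02 for 10 astrocyte genes, -0.02 for 10 oligodendrocyte genes and -0.13 for 13 microglia and leukocyte genes. They were -0.08 for 12 erythrocyte genes and -0.04 for 15 meninges genes. For tissues beside the brain they were -0.07 for 14 eye genes, -0.01 for 10 pituitary genes and -0.09 for 11 skeletal muscle genes. For processes they were 0.05 for 17 cell cycle genes, -0.14 for 9 immediate early genes, -0.02 for 17 glycolysis genes, -0.05 for 38 ribosomal protein genes, -0.03 for 25 proteasome genes, -0.03 for 13 sterol synthesis genes and 0.05 for 12 interferon genes. Camera adjusted p of these lists ran from 0.679 to 0.996. The camera direction was up although the median was below 0 for the oxidative phosphorylation, vessel, heat shock, pituitary, sterol synthesis, glycolysis and GABAergic lists.

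Among probe sets without a single gene name, 46 were higher in males, with a median difference of 0.82 (44 and 0.81 without the 2 virus probe sets among them), and 29 were higher in females, with a median of -2.77. The largest of these differences was -7.79 (SE 0.43, limma adjusted p = 9.22e-05), between means of 14.23 in females and 6.44 in males. Of the 29, 19 were higher in females by more than 2 on the log2 scale, and the median male level of these 19 was 6.02, against a median of 6.16 over virus probe sets. Of genes that the assembly does not place, an identifier under the name IPO11 was higher in males by 0.92 (SE 0.11), and NAGLU and an identifier under the name ZSWIM6 were higher in females. The IPO11 identifier on Z differed by 0.53 (SE 0.23, limma adjusted p = 0.625).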

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

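The tests of outlying arrays were fixed before the results were seen, and the splits at 1 unadjusted p were chosen afterwards. Dixon's gap to range ratio was computed for 98 groups of 5 arrays, and 6 exceeded 0.71, where chance gives about 4.9 at 1 in 20.

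SPTLC1 on female replicate 1 stood at 12.36 against 12.14 to 12.20 on the other females, a gap of 0.728 of the range. RLN3 on female replicate 5 stood at 11.55 against 11.03 to 11.17, a gap of 0.717 of the range. PIK3R6 on male replicate 5 stood at 7.16 against 8.06 to 8.22, a gap of 0.846 of the range. TBX2 on female replicate 5 stood at 6.37 against 8.11 to 8.79, a gap of 0.718 of the range. SPIN1L on female replicate 2 stood at 9.24 against 11.13 to 11.66, a gap of 0.780 of the range. NDUFS4 on male replicate 1 stood at 13.99 against 13.75 to 13.82, a gap of 0.739 of the range.

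Sex calls were also compared with 100 of the 126 splits of the 10 arrays into 5 and 5. The real split alone, 1 of 100, reached 247 probe sets higher in males (highest other split 3) and 60 higher in females (3). These counts were adjusted anew in each split and include the Z and W calls. They exclude a chance split for the calls as a whole, and do not test each direction or gene class apart. For gene classes every split was counted at the unadjusted p of 0.000878 that the real calls reach, since the adjusted cutoff moves with the Z and W calls. The real split alone reached 201 Z genes higher in males (highest other split 4) and 10 W genes higher in females (1), so a chance split is excluded there. The 5 autosomal genes higher in males were reached by 85 of 100 splits and the 13 higher in females by 10 of 100 (highest 18 for each), so for autosomal genes chance is not excluded. The count of chromosomes called by camera, 1, was reached by 82 of 100 splits (highest 3). The count of gene lists, 1, was reached by 75 of 100 (highest 5). With 5 arrays per sex, no split into 5 and 5 balances the sexes, so every split keeps part of the Z shift. Camera can call Z, or the list of mostly Z genes, in such splits too. For these counts the splits therefore cannot test chance, which is not excluded. The Z shift itself rests on the permuted index.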

How the results depend on the processing

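The highest pseudocount, the residual component as a covariate, the adjustment over autosomal genes alone and the 8 arrays without a block were tests chosen after the results were seen. Without a block, Z genes higher in males numbered from 133 to 234 over the settings, and the Z minus autosome index lay between 0.48 and 0.54. The index of Z genes with a W copy lay between 0.13 and 0.18 and that around DMRT1 between -0.24 and -0.08. Quantile normalization shared 195 Z genes of the 201 called, and the mean over probe sets shared 134. Of the 18 autosomal genes, 14 were shared after quantile normalization, 7 with the mean over probe sets and 5 with expressed probe sets only.

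With expressed probe sets only, 389 probe sets were higher in males, 27 higher in females and 5 W genes higher in females, where fewer features were tested. With trend and robust variance the counts were 399 probe sets higher in males and 1 autosomal gene higher in males. Without probe sets prone to cross-hybridisation they were 134 and 3, from fewer probe sets, and ZSWIM6 (the Z identifier) turned to 0.10. With the mean over probe sets, 3 autosomal genes were higher in males, LCT turned to -0.10 and CHIR-A2 to 0.22. With the residual component as a covariate, 21 autosomal genes were higher in females. With autosomal genes adjusted alone, limma called 0 in either direction (621 at an unadjusted p under 0.05). The contrast of bright and dim Z genes was -0.030 after quantile normalization and 0.079 at the highest pseudocount (exact permutation p = 0.00794 and 0.0238), 0.28 with no filter on dim genes and -0.20 with the filter that kept the brightest genes, which also widened the Z spread ratio to 4.46. Gene lists called numbered 2, with choroid plexus genes as the added list, after quantile normalization, autosomal centring, expressed probe sets only and the mean over probe sets, and 0 with Z members left out, which removes the called list. Fry called 3 chromosomes, Z, 4 and 8. The medians of 4 and 8, -0.019 and -0.028, lay near that of all autosomal genes, -0.026. Camera, which sets a chromosome against the other genes, gave them adjusted p = 0.633 and 0.607, so the fry calls do not set them apart from other autosomes. Apart from the cases where fewer features were tested, the cause was not tested.

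Leaving out 1 array at a time gave 1 to 5 autosomal genes higher in males, 6 to 19 higher in females and 1 to 2 gene lists. Autosomal genes higher in males fell to 1 without male replicate 3, 2 without female replicate 3 or 4 and 3 without male replicate 4 or female replicate 2. Those higher in females fell to 6 without male replicate 1 or 5 or female replicate 3 or 4 and to 8 without male replicate 2 or 4. The added list was choroid plexus genes without male replicate 1 or 2 or female replicate 3, and ribosomal protein genes (camera adjusted p = 0.00566) without male replicate 4. These calls used the preset correlation. With all arrays the ribosomal list had camera adjusted p = 0.679, and adjusted p = 0.998 with an estimated correlation. Of named genes, 37 missed the threshold in at least 1 setting, and NTRK2 passed in 2. The block below is among the settings and nearly sets the count of 37 on its own.

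The title of male replicate 1 gives no letter and no sex and letter A is on a female alone, so 8 arrays share letters. Deviations of the arrays with letter B, C, D and E correlated at 0.05, 0.11, 0.01 and -0.01 across genes. That shows no strong effect shared by a letter, and does not exclude a pairing. A replicate block over these 8 arrays called 0 probe sets higher in males and 2 higher in females, 0 Z genes, 0 autosomal genes in either direction and 1 W gene by limma, with 314 Z genes higher in males at an unadjusted p under 0.05. No Z share could be given there. The blocked indexes were 0.51 for Z, 0.15 for W copies and -0.18 around DMRT1, each at an exact permutation p of 0.125, the smallest possible. Without the block the same 8 arrays gave 121 probe sets and 133 Z genes higher in males, and 9 and 5 autosomal genes higher in males and females. Background near a log2 level of 6.16 limits what can be said of dim genes.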

Other observations

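The estimated correlation along the axis within the sexes, the draws of Z genes and the tests of gene length on Z, of the position of the DMRT1 window and of the unnamed probe sets were chosen after the results were seen, and the controls within groups of length or level, the autosomal length contrast and the noise estimate were chosen before theirs were.

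Some bright Z genes had nearly equal levels in both sexes. The brightest 12 of them were LMAN1L at -0.06 (SE 0.08), the astrocyte glutamate transporter gene SLC1A3 at 0.10 (SE 0.13), EDIL3 at -0.01 (SE 0.11), PIK3R1 at 0.10 (SE 0.06), CELF4 at 0.08 (SE 0.08), PLCXD3 at 0.02 (SE 0.07), the microtubule gene MAP1B at 0.01 (SE 0.07), SLC25A51 at -0.01 (SE 0.06), CTSV at 0.06 (SE 0.07), the glutamate receptor subunit gene GRIN3A at 0.05 (SE 0.10), ECPAS at -0.04 (SE 0.07) and LYRM7 at 0.04 (SE 0.11). With Z genes split into 3 groups by length, 8 of the 12 were in the longest group and 3 in the shortest. These genes were picked after their values were seen.

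The largest axis of variation within the sexes took 21.4% of the variance left after sex. Male replicate 1 scored 24.7 and female replicate 5 24.1, against -16.3 for male replicate 3 and -18.8 for female replicate 3. Within the sexes the scores correlated at -0.89 with the median log2 level of an array and at -0.77 with that of its virus probe sets. Ribosomal protein genes (38) were called lower along it by camera at the preset correlation (adjusted p = 2.6e-08) and not with an estimated correlation (adjusted p = 0.804).

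Z genes differed in the size of their sex difference, and gene length is a candidate source of part of this. With expressed Z genes split into 3 groups by length, the longest (149) had a median difference of 0.34 and the shortest (148) of 0.62, and the index contrast was -0.21 (exact permutation p = 0.00794), which 0 of 2000 random draws of Z genes reached. A length bias that differs between the sexes is argued against by the same contrast over autosomal genes, 0.00424 (exact permutation p = 0.825). Autosomal genes hardly differed by sex, so this contrast cannot test whether the arrays compress the ratios of long genes. A difference in expression level is argued against by the contrast within groups of like level, -0.22. Measurement noise alone is argued against by the noise-corrected SD, 5.98 times as large over Z genes as over autosomal genes. What about long Z genes goes with the smaller difference stays open.

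The smaller male excess around DMRT1 may reflect no more than a position along an uneven chromosome, since a share of 0.0887 of the overlapping windows had a median as low. Longer genes in the region accounted for a small part of it, since the deficit was -0.130 within groups of like length (exact permutation p = 0.0159) and -0.152 without them. Random draws of 40 Z genes had a central range of -0.131 to 0.132, and 38.4% of them gave a permutation p under 0.05. The length control therefore cannot say whether the deficit that is left exceeds chance among Z genes. Expression level would not account for the deficit, which was -0.18 within groups of like level. A local property of the region stays open.

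The unnamed probe sets higher in females may belong in part to W-linked transcripts. Of these 29, 4 (13.8%) shared a cluster number with a probe set of a W gene, against 0.0444% of 11271 unnamed probe sets, 311 times the share (292 times with the 687 virus probe sets left out), and the other 25 stay open. The 4 come from 2 clusters, and counted by cluster 2 of 24 matched against 3 of all 9069 (Fisher's exact p = 2.01e-05). Dim probe sets read higher on female arrays by little: the median difference of virus probe sets was -0.18, against -2.77 for the 29. Quantile normalization took the virus median to -0.03 and left that of the 29 at -2.65, with 27 of them past the limma threshold. Removing so small a shift could hardly have changed the 29, so the normalization adds no test. The 29 were also picked by their difference in the same arrays.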
